A study of Drosophila melanogaster with 2 samples.

How the data were processed

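ChIP-seq of schlank tagged with GFP was analysed in 2 biological replicates of whole embryos, per the labels. The deposited lists comprised 1 candidate list per replicate, 1 candidate list of both replicates pooled, and 1 thresholded set. Candidate lists hold peaks and background made as input for IDR, a method that ranks peaks by their reproducibility between replicates, and each had exactly 30000 entries. The thresholded set is the optimal IDR set made from the candidate lists, per the file list deposited with each library, and had 2790 peaks. All positions are on assembly dm6, per the labels. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. The file lists name a control for each candidate list, and the control data were not used here.

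The deposited signal column is the peak strength as the authors' peak caller gave it. Its scale is not stated, and it was used only to rank, filter and describe peaks within a list. The deposited −log10 q column had a ceiling, at 3.57 for 1870 thresholded peaks (67.0%), and was therefore not used for ranking. The summit is the peak start plus the deposited offset. Most candidates had 1 fixed width, 370 bp in replicate 1, 356 bp in replicate 2 and 364 bp in the pooled list. The thresholded set covered 873255 bp and the pooled candidates 10449251 bp. Its signal ran from 121 to 2915 with a median of 183. It held the 2790 strongest pooled candidates, with identical positions and signals. The background consisted of the 26849 pooled candidates whose interval overlapped no thresholded peak, which left out 361 others that did. A set ranked by the same signal that defines it can differ from weaker candidates in anything that moves with signal, GC content included.

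Samples were grouped by the antibody field. Read depth is unknown, so no interval rests on it. Intervals are 95% block bootstrap intervals (blocks of 500 kb, 1000 draws) and those of gene list odds ratios are exact, and both cover sampling of sites or genes in these lists, not variation between embryos. Peaks and genes, not replicates, are the units of every test.

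Annotation was Ensembl release 115 for BDGP6.54, and sequence was the NCBI Release 6 assembly. Arm names correspond to dm6, no summit lay beyond the end of its arm, and all peaks were on arms 2L, 2R, 3L, 3R, 4 and X. A promoter summit lies within 500 bp of the TSS of any annotated transcript, transposable elements left out. Shares were compared by two-sided Fisher's exact tests. For gene lists, protein-coding genes with a thresholded summit within 500 bp of a TSS were counted among those with a pooled candidate there, so a gene beside a divergent promoter can share its peak. For sequences, labels of peaks and background were permuted within promoter and other summits (100000 resamples, two-sided, drawn as hypergeometric counts, smallest p 2.0e-05), with matches on either strand within 100 bp. Benjamini-Hochberg adjustment was over 18 lists, 16 sequences or 7 annotation classes, with a threshold of 0.05. Promoter and other signals were compared by a permutation test of the difference of medians with 100000 resamples.

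The genes named were set by a rule: schlank, Lip3 and mag whatever their values, the protein-coding gene of the nearest TSS for the 25 strongest peaks with such a gene within 500 bp, and up to 4 members per list with the strongest promoter peak. Lists, sequences, tests and this rule were fixed before the data were examined. Other genes, sequences and checks are named as chosen later where they appear. RpL15, RpS2 and RpS3 were named after their values were seen.

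The alternatives were the stronger 50% of peaks by signal, each replicate alone, other promoter windows (250 and 1000 bp), protein-coding TSSs only, other backgrounds, sequence windows of 50 bp, and other definitions of shared peaks. Those added after the data were seen were GC strata for sequences and gene lists (bins of 5 percentage points) and the X share and annotation classes outside promoters.

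The tests were run on simulated data first. In 100 simulated gene sets with no raised list among 6674 genes, 5 had any list past the threshold. All 200 of 200 raised lists were recovered, with 3 of 1600 other lists called. Only the lists of cytoplasmic ribosomal proteins (77 genes) and oxidative phosphorylation (42 genes) were raised, both strongly. Recovery of shorter lists or smaller effects was not tested. The sequence test called 4 of 100 simulated sets of 2790 peaks with equal shares at an unadjusted p under 0.05, and 100 of 100 with shares raised 1.5 times. The simulated shares were close to those of the commonest sequences, so recovery of rarer sequences was not tested. GC content was not simulated, so calls that a GC difference between peaks and background can produce were not tested either. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.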

Results

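The binding sites of the ceramide synthase schlank, an enzyme of sphingolipid synthesis that also carries a homeodomain, were mapped by ChIP-seq in whole Drosophila melanogaster embryos of mixed sex aged 0 to 24 h. The embryos came from a transgenic line that stably expresses schlank with GFP fused to its C terminus. Chromatin was fragmented by sonication to 200 to 800 bp. The 2 samples were biological replicates of this 1 group, so no condition was compared with another. The antibody field of both samples names schlank, and separate controls are listed for them, but the free-text description of both calls them input controls. They are treated here as schlank ChIP because of the antibody field. Sequencing depth is unknown, because the lists hold peaks and their strengths but no read counts. The design raises 3 questions, namely how alike the replicates are, where in the genome the thresholded peaks lie, and which genes and sequences they mark.

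The strongest sites were largely shared by the 2 replicates. Of the 2790 strongest candidates of replicate 1, 59.4% (1658; 95% block bootstrap interval 57.3 to 61.5) had a summit within 200 bp of one of the 2790 strongest of replicate 2. Randomly drawn candidates shared 3.63% on average and 5.05% at most over 1000 draws (one-sided permutation p = 0.001, the smallest these draws can give). The promoter of CG14100 carried the strongest thresholded peak and had a signal of 872 in replicate 1 and 2048 in replicate 2, the maximum of each list. Ugalt, which encodes a UDP-galactose transporter, had 581 and 1935. The signal is the authors' own value per peak. Its scale differs between the lists, so its size is not compared between the replicates.

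Of the thresholded peaks, 95.1% (94.2 to 95.9) had a candidate within 200 bp in replicate 1 and 99.5% (99.3 to 99.8) in replicate 2. The thresholded set held the strongest candidates of the pooled list, to which both replicates contributed, so these shares are not independent of how it was made. Among the 2790 strongest candidates of a replicate, the shares were 71.7% and 86.7%. Across the 2640 thresholded peaks with a candidate in both, the signals of the replicates correlated with Spearman's rho 0.43 (0.39 to 0.46) and Pearson's r of log2 signal 0.55 (0.51 to 0.58). Over all 11161 candidates shared by the replicates, a set not restricted to strong pooled signal, rho was 0.57 (0.55 to 0.58). These coefficients are across peaks, which are not independent replicates. The sequence under the candidates differed between the replicates. Mean GC content within 100 bp of the summit was 39.7% in replicate 1 and 44.6% in replicate 2, a difference of -4.83 percentage points (95% block bootstrap interval -5.0 to -4.67).

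**Figure D1:**
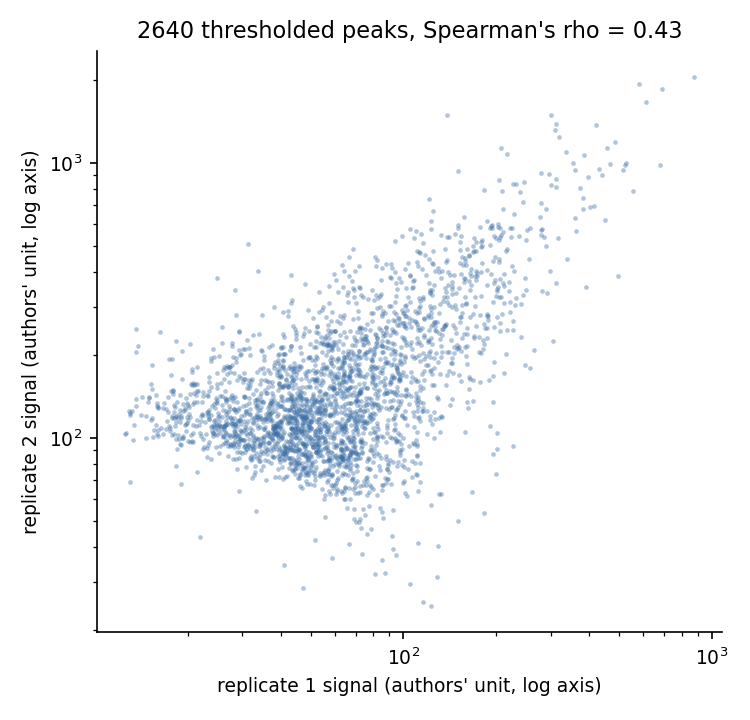
Signal of replicate 1 (x axis) against replicate 2 (y axis), both on log axes in the authors' unit, with 1 point for each of the 2640 thresholded peaks that had a candidate in both replicates. The strongest peaks of one replicate are strong in the other, and the cloud of weaker peaks is wide (Spearman's rho 0.43).

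**Figure D2:**
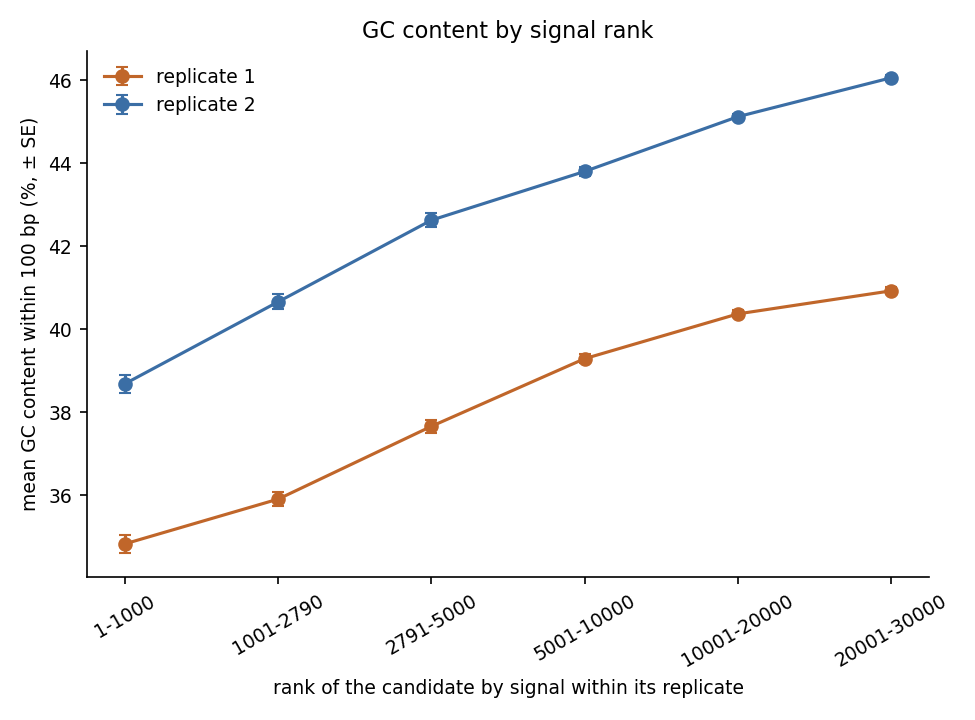
Mean GC content within 100 bp of the summit (y axis, percent, bars are the standard error across candidates) by rank of the candidate's signal within its replicate (x axis). GC content rises from 34.8% to 40.9% in replicate 1 and from 38.7% to 46.1% in replicate 2 between the strongest and the weakest candidates.

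The tagged gene was itself marked. schlank (FBgn0040918, dm6 chromosome X, 6257668 to 6267228, minus strand) held 3 thresholded summits in introns and had a further one upstream of its TSS. The strongest lay in an intron at 6265626 with a pooled signal of 507, and both replicates had a candidate there, with signals of 179 and 329. The other intronic summits were at 6263810 (signal 258) and 6264625 (signal 176). The upstream summit, at 6267572 (signal 225, rank 985 of 2790), lay 344 bp from the TSS of schlank and 225 bp from that of the divergent gene Spt6, which encodes a transcription elongation factor. Replicate 2 had candidates near that upstream summit (signal 203) and near the intronic summit at 6264625 (signal 169), and replicate 1 had none within 200 bp of either. Of 2536 protein-coding genes of 4.78 to 19.1 kb, 98.1% held fewer thresholded summits than the 3 of schlank. Its span was also rich in candidates, with 8 in the pooled list, 7 in replicate 1 and 9 in replicate 2. Fewer were held by 92.4%, 92.3% and 94.1% of these genes, whose median was 2 in each list. The number of copies of the locus in the transgenic line was not measured here. The 101 bp centred on the strongest summit (X, 6265576 to 6265676) read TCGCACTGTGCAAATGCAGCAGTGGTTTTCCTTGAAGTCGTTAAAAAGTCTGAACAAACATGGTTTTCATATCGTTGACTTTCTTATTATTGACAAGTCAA, with a GC content of 36.6%.

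**Figure D3:**
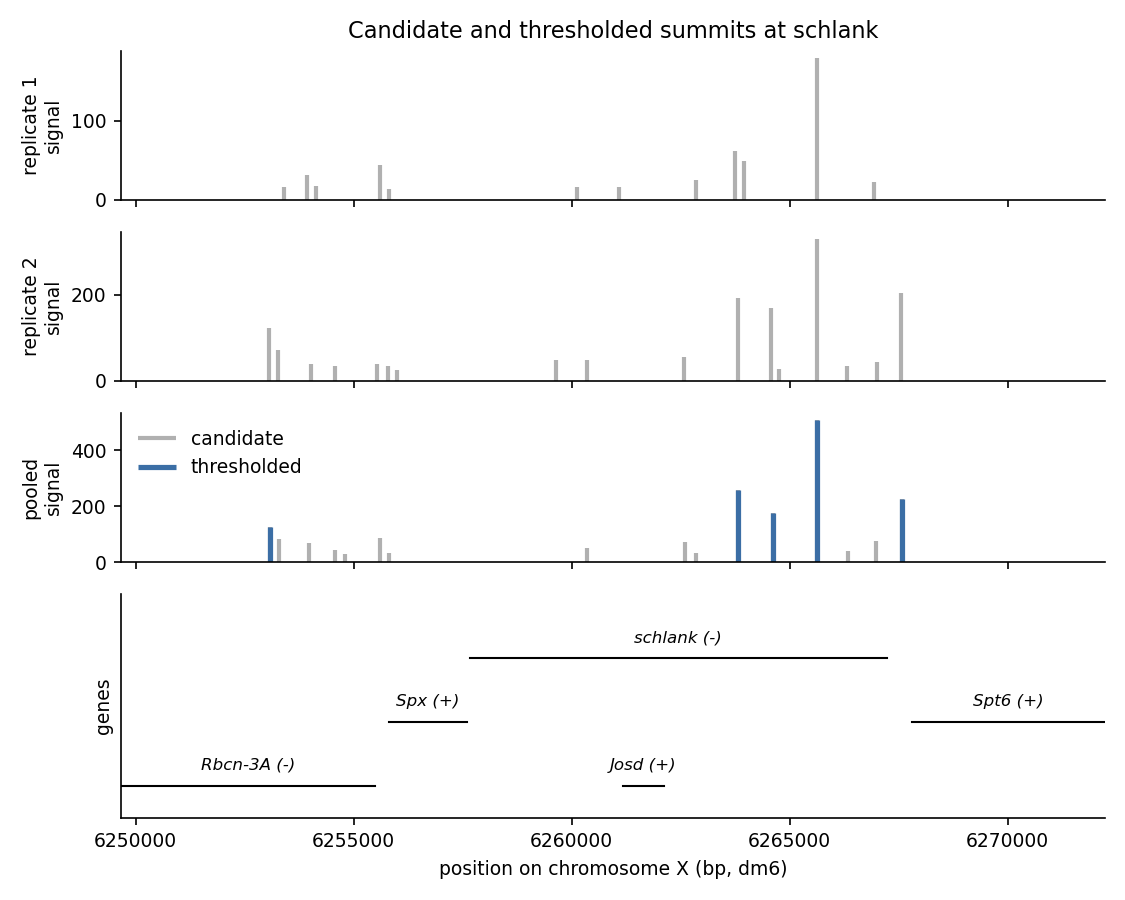
Map of the schlank locus on chromosome X (x axis, bp, dm6). Vertical lines give the signal (y axis, authors' unit) of every candidate summit in replicate 1, replicate 2 and the pooled list, with thresholded summits in blue, and gene spans with their strands are drawn at the bottom. The highest line in each panel marks the intronic site whose pooled summit is at 6265626, with signals of 179 in replicate 1, 329 in replicate 2 and 507 in the pooled list.

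Lip3 and mag, a pair of lipase genes fixed in advance for their link with schlank, carried no thresholded peak. Lip3 (3R, 13370240 to 13371904) had a pooled candidate with a signal of 33.5, 10 bp from its TSS, and one with a signal of 47.7 beyond the far end of the gene (summit 13369854, 2050 bp from its TSS), against 121 for the weakest thresholded peak. mag (3L, 20460683 to 20462274) had no pooled candidate within 500 bp of its span. Replicate 1 had 1 there, with a signal of 13.5, which lay beyond the far end of the gene (summit 20462430, 1747 bp from its TSS).

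Thresholded peaks concentrated at promoters. Of the 2790 summits, 1472 (52.8%, 50.6 to 55.0) lay within 500 bp of an annotated TSS, compared with 25.5% (24.6 to 26.5) of the 26849 candidates that overlapped no thresholded peak. The odds ratio was 3.26 (95% block bootstrap interval 2.97 to 3.56; two-sided Fisher's exact p = 7.0e-184). The median distance to the nearest TSS was 408 bp, against 1760 bp for the other candidates. Among promoter summits, 75.9% lay upstream of the TSS, with a median position of -91 bp. Peaks at promoters had a median signal of 192 and other peaks 176, a difference of 16.2 (two-sided permutation p = 7.0e-05). With a promoter window of 250 bp the difference was 7.96 (permutation p = 0.035).

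The strongest peaks at promoters of protein-coding genes lay at genes of varied function. After CG14100 (3L, summit 19590616, signal 2915, 92 bp from the TSS) and Ugalt (X, summit 2703893, signal 2506, 41 bp) came CenG1A (signal 1701), the Polycomb group gene ph-p (1668), the mitochondrial ribosomal protein gene mRpL41 (1656) and CG1888 (1617). The translation factor gene eIF6 (1558), the arginine methyltransferase gene Art3 (1498), px (1458) and the chromatin protein gene Chro (1453) followed. PNPase, amon, Pdrg1, CG9147, Atf3, Alg3, CG11309, RpS27, Gapdh2, Tcs5, CG1635, larp, RpL7, CG5611 and MFS10 completed the 25 strongest of these, with signals between 1427 and 1063. The peaks ranked 11 and 13 of all lay at the promoters of the non-coding genes lncRNA:CR44619 (signal 1571, 460 bp from the TSS) and lncRNA:CR31840 (signal 1534, 22 bp). The peaks ranked 2, 4, 5 and 6 of all lay in introns. The strongest of these, with a signal of 2550, was on 2L (summit 6612714), 1027 bp from the nearest TSS.

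Coding exons were nearly free of thresholded summits, with 6 (0.215%) compared with 6.61% of the other candidates (odds ratio 0.0304, adjusted p = 4.9e-68, Fisher's exact test, Benjamini-Hochberg over 7 classes). Introns held 34.8% of thresholded summits and 43.8% of the others, and intergenic sequence 9.32% and 19.6%. Promoter windows took precedence in this classification, so their larger share lowers those of the other classes. The other classes were therefore also compared among the 1318 thresholded summits and 19995 other candidates outside promoter windows, a comparison added after the data were seen. Coding exons remained low there, with 0.455% against 8.88% (odds ratio 0.0469, adjusted p = 2.1e-41, Fisher's exact test, Benjamini-Hochberg over 6 classes). Introns held the larger share in the thresholded set, with 73.7% against 58.9% (odds ratio 1.96, adjusted p = 5.3e-27, exact test). Intergenic sequence held 19.7% against 26.4% (odds ratio 0.686, adjusted p = 1.1e-07, exact test), and exons of non-coding genes 2.28% against 1.29% (odds ratio 1.79, adjusted p = 0.0066, exact test). The shares of 3' UTRs (2.35% and 3.17%) and 5' UTRs (1.52% and 1.44%) did not pass the test there (adjusted p = 0.12 and 0.81, exact tests). At tRNA genes, 9 thresholded summits (0.323%) compared with 0.264% of the others, a difference that was not detectable (Fisher's exact p = 0.56). None of these comparisons held GC content equal, although thresholded summits were poorer in GC (38.5%) than the other candidates (43.6%).

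**Figure D4:**
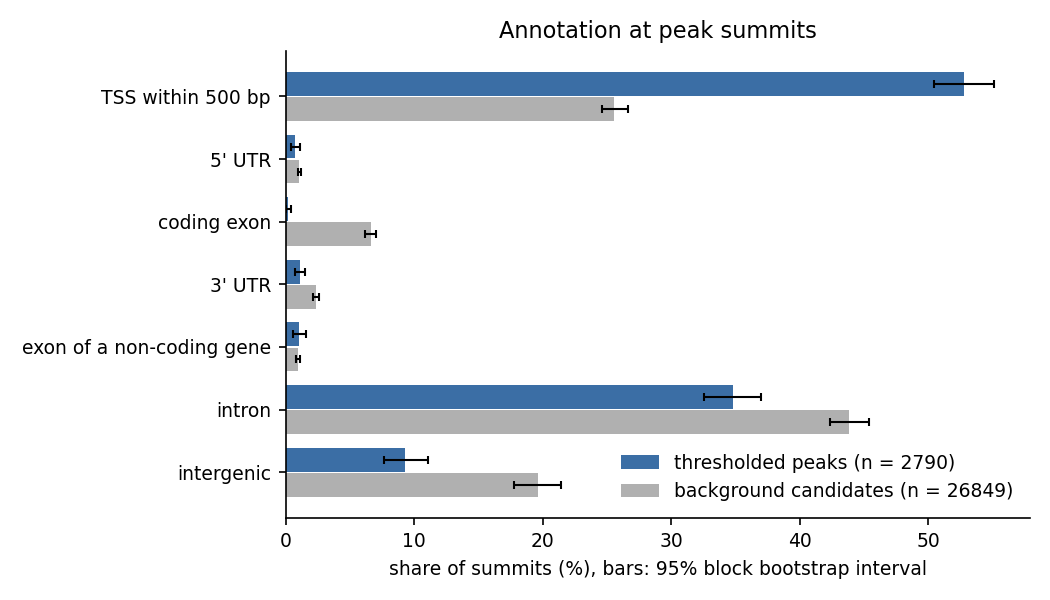
Share of summits (x axis, percent) in each annotation class for the 2790 thresholded peaks and the 26849 background candidates, with 95% block bootstrap intervals. The class within 500 bp of a TSS takes 52.8% of thresholded peaks and 25.5% of the background, and coding exons 0.215% and 6.61%.

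The X chromosome held more thresholded peaks than its share of candidates, and this was seen outside promoters. X had 498 peaks (17.8%), compared with 14.4% of the other candidates (odds ratio 1.29, block bootstrap interval 1.11 to 1.48, Fisher's exact p = 2.1e-06). X makes up 17.6% of the length of the arms, so over all peaks the excess is relative to the candidates, of which X held 14.7% in the pooled list, and not to length. Among peaks away from promoters the shares were 20.9% and 14.1% (odds ratio 1.61, 1.36 to 1.90), and among promoter peaks 15.1% and 15.4% (odds ratio 0.979, 0.802 to 1.16). The ratio of these odds ratios was 1.64 (1.31 to 2.07). Arm 3L held fewer, with 18.9% against 22.7% (odds ratio 0.794, Fisher's exact p = 3.6e-06).

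Genes of cytoplasmic ribosomal proteins were marked far more often than other genes. Of the 6674 protein-coding genes with any candidate at a TSS, 1776 (26.6%) had a thresholded peak there, but 64 of 77 ribosomal protein genes did (83.1%). The odds ratio was 14.0 (95% interval 7.63 to 27.9; adjusted p = 4.9e-24, Fisher's exact test, Benjamini-Hochberg over 18 lists). The median signal of the strongest promoter peak of these 64 genes was 349 (quartiles 255 and 495). RpS27 (3R, summit 25247511, 3 bp from the TSS) had a signal of 1200, RpL7 1085, RpL34b 646 and RpS28b 639. Another 13 of the genes had only a candidate, among them RpL15, RpS2 and RpS3, and 10 had no candidate at a TSS.

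Cuticle genes of the epidermis went the other way, with no thresholded peak at any of the 20 that had a candidate (adjusted p = 0.033, Fisher's exact test). A count of 0 of 20 allows a share of up to 15%. This call was lost without replicate 2, where 1 of 17 had a peak (odds ratio 0.147, adjusted p = 0.19, exact test). In the stronger 50% of peaks and with a promoter window of 250 bp the counts were 0 of 20 and 0 of 10, which give unadjusted p = 0.060 and 0.072 (exact tests), so a lower share could not have passed there.

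None of the other lists passed the test, including those for sphingolipids and other lipids, and none passed in an alternative. Many held few genes, so each odds ratio is given with its range over the peak sets, promoter windows and backgrounds tried, this value included. Of ceramide and sphingolipid genes, 6 of 16 had a promoter peak (odds ratio 1.66, interval 0.494 to 5.04; adjusted p = 0.79, exact test). The odds ratio was below 1 without replicate 2 and with a promoter window of 250 bp, both with 3 of 15 (odds ratios 0.590 and 0.692), and higher in the stronger 50% of peaks (2.59) and with a window of 1000 bp (2.25). The genes with a peak included the lipid phosphatase gene wun (signal 595), egh, a glycosyltransferase gene of glycosphingolipid synthesis (485), and lace, which encodes a subunit of serine palmitoyltransferase (193). They also included schlank itself (225), through the upstream summit that lay nearer to Spt6 and had no replicate 1 candidate. Lipase and lipid storage genes had 6 of 24 (odds ratio 0.919, range 0.919 to 1.47, and 1.18 without replicate 2), among them Seipin (391), Lpin (314), Gpat4 (237) and Agpat4 (214). The Seipin summit had no replicate 1 candidate within 200 bp. Fatty acid and SREBP pathway genes had 6 of 16 (odds ratio 1.66, range 0.811 to 2.29, and 1.05 without replicate 2), among them Hmgs (192), Baldspot (185), eas (176) and AcCoAS (173). The intervals of these odds ratios reached from 0.298 to 5.04, so moderate differences could not be detected with lists of this size.

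The other housekeeping lists had odds ratios of 0.590 to 1.84, none of which passed the test. Oxidative phosphorylation genes had 8 of 42 (odds ratio 0.647, interval 0.258 to 1.43, range 0.553 to 1.14, the highest without replicate 2), with ND-ASHI (695) and ND-MWFE (305) highest, and proteasome genes 3 of 17 (odds ratio 0.590, range 0 to 0.708, and 0.197 without replicate 2), namely Rpn3 (152), Rpn5 (149) and Prosalpha4 (144). DNA replication and cell cycle genes had 9 of 35 (odds ratio 0.954, range 0.699 to 1.47), among them Dref (578), which encodes a transcription factor of replication genes, Dp (468), dpa (237) and dup (228). Heat shock and chaperone genes had 6 of 15 (odds ratio 1.84, interval 0.538 to 5.80, range 1.09 to 2.40, the lowest without replicate 1), among them Hsp83 (1054), Hsp27 (549), Hsc70-5 (246) and Hsc70-4 (149).

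Embryonic patterning genes had 4 of 28 (odds ratio 0.458, range 0.243 to 0.536, the lowest without replicate 2), namely Dll (237), hb (196), tin (146) and dl (132). Germline genes had 5 of 12 (odds ratio 1.97, range 0.985 to 1.97), with bgcn (381), orb (199), CycB3 (133) and gcl (130) highest, but the odds ratio was 1.00 without replicate 1 and 0.985 without replicate 2. Neuronal genes had 3 of 16 (odds ratio 0.636, range 0.548 to 1.31, and 1.00 without replicate 1), namely elav (777), Nrx-1 (419) and shot (196), and glial genes 1 of 6 (0.551, range 0.428 to 1.5, the highest without replicate 1), moody (966). Muscle genes had 5 of 23 (0.765, range 0.369 to 1.14), with Msp300 (496), sls (361), mbc (192) and rols (137), and hemocyte genes 3 of 10 (1.18, range 0.599 to 1.66, with 0.599 without replicate 1 and 0.644 without replicate 2), namely ush (207), LanB2 (194) and Nplp2 (139). Gut genes had 2 of 15 (0.424, range 0.421 to 0.874, and 0.675 without replicate 2), namely fkh (782), the founding forkhead transcription factor gene, and Vha16-1 (192). Tracheal genes had 2 of 9 (0.788, range 0.236 to 0.857, the lowest without replicate 2), namely trh (227) and mmy (122), and fat body genes 1 of 7 (0.459, range 0 to 0.693, and 0 without replicate 2), DNaseII (122). The summits named for gcl and DNaseII had no replicate 1 candidate within 200 bp.

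**Figure D5:**
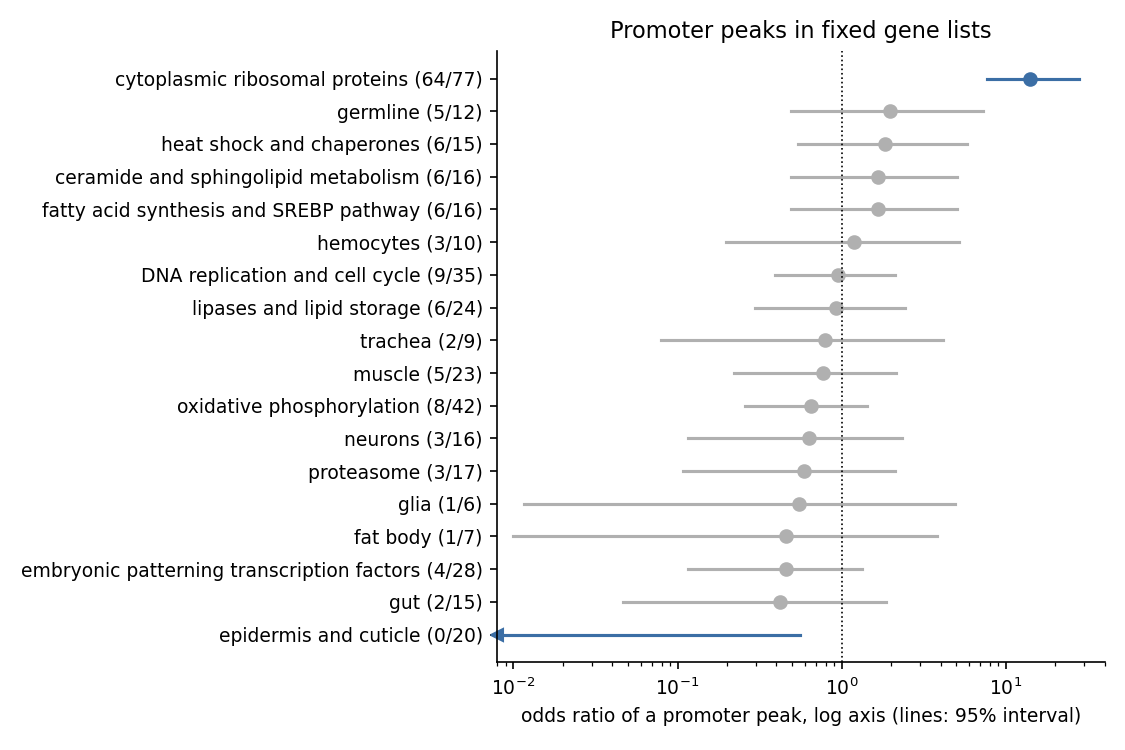
Odds ratio of a thresholded promoter peak (x axis, log scale) for the 18 gene lists, with 95% intervals, and the number of genes with a peak over the number with a candidate in brackets. Lists past the test are in blue, the ribosomal protein list is at 14.0, and the arrow marks the cuticle list, whose odds ratio of 0 lies beyond the axis.

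Homeodomain-type sequences were more frequent under thresholded summits than expected from their promoter share. TAATTA, the core of many homeodomain sites, occurred within 100 bp of 14.6% of summits, against 11.3% expected (ratio 1.30, adjusted permutation p = 0.00011). TAATGA had a ratio of 1.16 (adjusted permutation p = 0.0043). Thresholded summits were also poorer in GC, with 38.5% ± 7.35 (SD across 2790 peaks) against 43.6% ± 7.80 (SD across 26849 candidates). Within strata of promoter class and GC content, a test added after the data were seen, both ratios fell below 1 and neither passed (0.977 and 0.964, adjusted permutation p = 0.78 and 0.76).

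Other sequences with higher shares were the GAGA factor repeat (ratio 1.29, adjusted permutation p = 0.0025), the Dref site TATCGATA (1.47, 0.00048), the TATA box (1.47, 0.00011) and core promoter motif 7 (1.22, 0.0085). In the GC strata the GAGA repeat (1.61) and core promoter motif 7 (1.26) passed, but Dref (1.2) and the TATA box (1.03) did not (adjusted permutation p = 0.19 and 0.78). GAGA also lost its call without replicate 2 (ratio 1.06) and core promoter motif 7 without replicate 1 (ratio 1.13) and in the stronger 50% of peaks (1.19). With windows of 50 bp, the GAGA repeat (1.04), core promoter motif 7 (1.14) and Dref (1.39) did not pass (adjusted permutation p = 0.98, 0.33 and 0.073). Against windows 1000 bp to the right of the same summits, TAATGA (1.02), the GAGA repeat (1.06) and CA repeats (0.944) did not pass (adjusted permutation p = 0.77, 0.48 and 0.53). Expected shares are taken over peaks and background together. These windows are only as many as the peaks, which pulls all ratios against them closer to no difference. The size of those ratios is therefore not comparable with that of the others. The shifted windows also kept the promoter class of their unshifted summits, so promoter class was not held equal in that comparison. Lower shares were found for CA repeats (ratio 0.701, adjusted permutation p = 0.00011) and CTCC repeats (0.387, 0.035), and neither passed in the GC strata (0.900 and 0.629), nor did CTCC repeats without replicate 2 (0.533), with windows of 50 bp (0.559) or against windows 1000 bp to the right (0.476, adjusted permutation p = 0.066). The other 8 of 16 sequences did not pass, among them those of BEAF-32, Zelda, M1BP, CTCF and the sterol response element. The CTCF site had a ratio of 1.71 (adjusted permutation p = 0.13) but lay at only 13 summits. Its ratio was 1.44 to 2.15 in the alternatives, none of which passed. With so few matches, the result does not show that its share was equal. The M1BP site (ratio 1.29, adjusted permutation p = 0.14) did pass without replicate 1 (1.48, 0.015) and against windows 1000 bp to the right (1.79, 8.0e-05). It occurred in 0.204% of the shifted windows of promoter summits, against 2.00% of promoter background candidates. The latter call therefore compares promoters with sequence largely outside them.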

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

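Of 108 values recomputed under alternatives, 77 kept their direction and their side of the threshold, or stayed within the spread or 1.5 times of the count. The promoter share (42.9% to 64.3%, above background in every alternative), the tRNA share and the replicates' overlap (44.3% to 61.4%) did so throughout. So did the ribosomal protein list (odds ratios 10.8 to 19.7, and 3.15 times the expected count in GC strata). The X share did so too, at 17.0% to 20.1% with promoter peaks included and 20.9% outside promoter windows. Promoter peaks alone were not among the alternatives and showed no X excess (15.1% against 15.4%). The signal difference at promoters kept its direction and call, at 7.96 to 20.8 in the pooled list. It was 11.6 without replicate 1 and 8.20 without replicate 2, on the scales of single lists. The GC strata, the X share and the annotation classes outside promoters were tests chosen after the data were seen. Outside promoter windows, which otherwise take precedence, introns (73.7%) and 5' UTRs (1.52%) lay above the background in place of below it, 3' UTRs (2.35%) no longer passed and exons of non-coding genes (2.28%) did. The number of gene lists past the threshold in either direction was 2, and it was 1 in the stronger 50% of peaks and with a 250 bp window, and 1 to 2 without a replicate. The lost list was the cuticle list. With the stronger 50% and at 250 bp its count was already 0, too few to pass, and the cause of the loss without replicate 2 was not tested. The number of sequences with a higher share was 6, and it was 3 with 50 bp windows, where GAGA, Dref and core promoter motif 7 were lost and the cause was not tested, and 2 in GC strata, where TAATTA (0.977) and TAATGA (0.964) fell below 1, as GC content was held equal there. The rank correlation of the replicates was 0.52 with summits within 50 bp, which leaves 1948 of 2640 peaks, and 0.44 in the stronger 50% of peaks. Single lists or sequences that lost their call kept their direction in 19 cases. The planned restriction to the 6 main arms removed nothing, as all peaks lie on them, and gave no value. No paired analysis was possible because there is 1 group. Depth is unknown, so its effect on any value was not tested.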

Other observations

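The genes, sequences and tests of this part were chosen after the data were seen, except the tests of GC content and TSS number at ribosomal protein genes and of GC content between the replicates, whose bounds were set before their results were seen. Some genes held clusters of thresholded summits. The gene shn, which encodes a zinc finger transcription factor of the Dpp pathway (2R, 11159086 to 11217394), held 16 in its span, and CHES-1-like, which encodes a forkhead transcription factor (X, 7682338 to 7709385), held 13. Raf, which encodes a MAP kinase kinase kinase, bun and CG1677 held 9 each, and ush, which encodes a GATA cofactor, held 8. Of the 28 protein-coding genes with at least 5 summits, 9 were on X. Their densities ran from 1.52 per 100 kb in kirre to 48.1 in CHES-1-like, against 2.08 over all arms, so some are listed for their length, and the overlapping genes CG45088 and CG6191 share their 5 summits.

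The sequence GTAAAYA, the core of forkhead sites, lay within 100 bp of 576 thresholded summits (20.6%, 19.3 to 22.0). From promoter class 12.9% were expected (ratio 1.60), and from promoter class and GC content together 15.2% (ratio 1.36). The sequence was present at 18.1% of promoter and 23.4% of other summits. Among the 2790 strongest candidates of each replicate alone it was at 613 in replicate 1 and 557 in replicate 2, with ratios to expectation in promoter and GC strata of 1.47 and 1.36.

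Among 7-base words on the arms of chromosome 2, GTAAATA had rank 1, GCAAATA rank 2 and GTAAACA rank 3 by Fisher's exact p of summits against flanks 400 bp away. The first and last were followed because they match GTAAAYA, not by rank, and were tested on the other arms, although these had contributed to their being noticed. There, GTAAAYA remained in excess with GC content held equal, with a ratio of 1.30 within promoter and GC strata (permutation p = 2.0e-05, the smallest possible). Whether GC content of the peaks is the whole source is not decided by this, because these arms had helped to choose the words. Base composition of the words also stays open. Both lay above every rearrangement of their letters (percentile 100), but they had also led the list over all arms, so their choice largely sets that outcome. Which proteins occupy these sites was not tested.

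At ribosomal protein promoters, GC content is argued against as the whole cause by an observed count 3.15 times that expected within GC strata, and the number of annotated TSSs by 3.01 times within strata of TSS number (permutation p = 2.0e-05 for both, the smallest possible). Capture at any strongly transcribed promoter remains open. Oxidative phosphorylation and mitochondrial ribosomal protein genes (15 of 45, odds ratio 1.38) had upper bounds of at most 2.66, below the lower bound of 7.63 of the ribosomal protein list, and translation factor genes had 13 of 34 (odds ratio 1.71, 0.786 to 3.59). But transcription was not measured here, and ribosomal protein genes may be transcribed more strongly than these. No biological explanation was tested, since the design has 1 group.

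The replicates differed in GC content at every rank, as the plot of GC content by rank shows. Their rank correlation was 0.43 (0.39 to 0.46) plain and 0.47 (0.44 to 0.50) once GC content was held equal. The latter value lay just above the interval of the plain one, the bound set beforehand for an effect of GC content. The intervals overlap and no interval of the change was taken, so whether GC content lowers the correlation is not decided. Across the thresholded peaks shared by both, signal and GC content correlated with rho -0.32 in replicate 1 and 0.054 in replicate 2, while over all candidates the stronger ranks had lower GC content in both. Chromosome 4 held 483 candidates in replicate 1 (1.61%, exact binomial interval 1.47 to 1.76) and 74 in replicate 2 (0.247%, 0.194 to 0.310). Among the 2790 strongest of each, it held 15 (0.538%, 0.301 to 0.885) and 7 (0.251%, 0.101 to 0.516). GC content within 100 bp of the summit is argued against as the source of that gap. The share in replicate 1 over all candidates was still 6.35 times that of replicate 2 reweighted to the same GC content (5.45 to 9.69). That interval rests on 3 blocks of chromosome 4. Chromosome 4 is also the arm poorest in GC (35.2%, the others 41.6% to 42.6%), and replicate 1 had the candidates poorer in GC. An effect of GC content over longer stretches was not tested and stays open. A difference in library or input between the replicates stays open and was not tested.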
